A study of Mus musculus with 2 samples.

How the data were processed

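The data are 1 RNA library and 1 antibody tag library from the same droplets, made by the submitters from LSK cells (lineage-negative, Sca-1+, Kit+) of pooled mouse bone marrow. Per the labels' protocols, cells enriched for Kit were stained with fluorescent antibodies, sorted, stained with TotalSeq-A antibodies for 30 minutes, loaded in 1 port of a 10x Genomics instrument and sequenced to a planned 50000 reads per cell for RNA and 10000 for tags. The labels speak of 65 antibodies, and the matrix holds 67 tags. The labels give 4 pooled mice in one sentence and 3 male mice in another, and the difference is left as it stands. Per the submitters' processing notes, the reads were processed with Cell Ranger on mm10. The versions and settings are not given in the sources used here.

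The deposited matrix holds raw UMI counts per gene or tag and barcode, with no normalization, as its whole values and header show. The deposited clusters come from ICGS2, per the file's name, and the genes and settings used for them are not given in the sources used here. They list 10832 barcodes, of which 10828 are in the matrix and 4 are not, and 1558 barcodes of the matrix are in no cluster. Gene symbols and identifiers were taken from the deposited feature table, and gene positions from the RefSeq annotation of GRCm38.p6, the assembly also called mm10. Only the 10828 clustered barcodes entered the main values, with no further filter on cells.

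Counts of a gene were summed over the cells of a group and given as counts per 1000000 RNA UMIs of the group (CPM), and tag counts per 10000 tag UMIs. Cell cycle RNA is the sum of the S phase list and the G2 and M phase list per 10000 UMIs. Cells from 1 pool are not replicates, so no test was run and no p-value was computed. A level has an exact 95% Poisson interval, a share an exact Clopper-Pearson interval, and a ratio of summed counts the exact conditional binomial interval. The interval of a list's median comes from 500 Poisson draws. All intervals cover counting error only. A gene was measured when it had at least 20 UMIs over both groups, and counted as higher or lower from a ratio of 1.5, and a group at 0 counts was set to 3 counts in a ratio.

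The gene lists, the rule for named genes, the main settings and all but 13 of the alternatives were chosen before the data were examined. The 21 lists are stem cell (26 genes, 25 in the matrix), lymphoid priming, granulocyte-monocyte priming, megakaryocyte-erythroid priming, mast-basophil-eosinophil, dendritic cell, S phase, G2 and M phase, quiescence, G1 cyclins and kinases, ribosome biogenesis, glycolysis, oxidative phosphorylation, immediate early and heat shock, interferon response, mature B cell, mature T and NK cell, neutrophil, erythroid, monocyte and macrophage, and endothelial and stromal genes. By the rule, members of these lists could be named, and outside them the 10 genes with the largest ratio in each direction among those of at least 50 CPM on the higher side. Ribosomal protein, mitochondrial and unnamed genes were left out. For each cluster the 5 genes with the largest ratio to the mean of the other clusters were named as its description. The macrophage list (10 genes, 2 of them also in another list) and the plasma cell list (10 genes) were written after the data had been seen, and so were the comparisons of cluster 6 with clusters 1 and 11 and of cluster 3 with cluster 1.

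CD135 tag levels were compared as the centred log ratio over all tags of a cell, and cells were split into 3 equal parts, with borders at 0.525 and 1.22. For the split by CD135 and CD150, a mixture of 2 normal distributions was fitted to each tag, with borders at 0.740 and 0.272. A CD48 tag had been planned as well, but no CD48 tag is in the matrix, so the subsets rest on CD135 and CD150. In place of the tag, an alternative thinned all cells as below and left those with a Cd48 UMI out of the CD135− CD150+ side. Where the detection of a gene per cell was compared between groups, each cell was thinned at random to 4000 UMIs. Shares for the leading genes of a cluster, and those given beside a thinned share, rest on all UMIs. The depth of 4000 is the 10th percentile of the cells' totals, rounded down to a multiple of 500. Thinning to it left out 642 of the clustered cells. At the alternative depth of 5500 UMIs it left out 2448. Cells with little cell cycle RNA are those with at most 13 such UMIs after thinning, the lowest part of a split into 3, which with ties held 35.8% of cells. Inside the Flt3 RNA-positive cells the split into 3 was made anew. Flt3 was left out of the lymphoid list except in the comparisons between clusters, where medians without it stand beside the main ones.

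Doublets were called with Scrublet in scanpy, at an expected share of 10% and 30 principal components, over all barcodes. It marked 1645 of 12386 barcodes (13.3%, 12.7% to 13.9%) and 1471 of the clustered ones (13.6%). They stayed in the main values, since the authors' clusters hold them, and their removal is an alternative. The other alternatives were all barcodes, a filter of at least 1000 genes and under 10% mitochondrial UMIs, the mean of each cell's CPM, totals without ribosomal protein and mitochondrial genes, thinning, a log scale of tag counts per 10000, the outer 25% of cells by tag on each side, ratios within clusters, gene minimums of 5 and 100 UMIs, cells with much cell cycle RNA left out, the 25th percentile as thinning depth, the median of each tag as border and, chosen after the data had been seen, clusters 2 and 7 left out.

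The calculation of ratios was tested on simulated counts for the comparison of cluster 6 with cluster 1, over 9355 genes with 200 changed. The true fold lay inside the interval for 94.5% of genes changed 1.5-fold, 97.5% of genes changed 2-fold and 96% of genes changed 4-fold. The simulated counts were Poisson draws, which the intervals assume. They check the calculation only, and not how well the intervals hold for genes whose UMIs sit in few cells. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0 and Matplotlib 3.10.9.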

Results

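LSK cells are mouse bone marrow cells that lack markers of mature lineages and carry Sca-1 and Kit, the population that holds blood stem cells and multipotent progenitors. The data come from 1 pool of wild-type C57Bl/6J bone marrow, in which RNA and antibody tags were counted in the same droplets (CITE-seq). The pool gave 1 RNA library and 1 antibody tag library. The labels name a pool of 4 mice aged 2 months, while the staining text in the same labels speaks of 3 male mice. Of 20000 sorted cells 16000 were loaded, and the matrix holds 12386 barcodes with 114157743 RNA UMIs (unique molecular identifiers, each standing for 1 captured molecule) over 28692 genes and 13730431 tag UMIs over 67 antibodies. The authors placed 10828 of these barcodes in 11 clusters, numbered but not named, and left 1558 outside. A clustered cell had a median of 7953.5 RNA UMIs, 2598 genes and 972 tag UMIs. All mice share the pool, so no value below has a replicate check. The intervals are exact 95% Poisson or binomial intervals, or intervals of a ratio drawn from them, and cover counting error only.

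Flt3 RNA was highest in cluster 6 and lowest in cluster 3, and cluster 6 was at the same time among the clusters with the least cell cycle RNA. Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489 on mm10) codes for a receptor tyrosine kinase known as CD135 on the cell surface. Cluster 6 held 299 CPM of Flt3 (counts per 1000000 RNA UMIs, 287 to 311), cluster 11 held 261 (247 to 275), cluster 1 held 123 (116 to 130) and cluster 3 held 39.4 (34.6 to 44.7), which put cluster 6 above cluster 3 by 2.92 on the log2 scale (2.73 to 3.12). The CD135 tag, which reads the protein, was highest in cluster 11 at 204 of 10000 tag UMIs (200.1 to 208), followed by cluster 6 at 159 (157 to 162), and lowest in cluster 3 at 28.8 (27.7 to 30.1). The tag range from cluster 11 to cluster 3 was 2.82 on the log2 scale (2.76 to 2.89).

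The sum of 41 S phase genes and 52 G2 and M phase genes gave the cell cycle RNA of each cluster. Clusters 1 and 6 held 26.1 (25.8 to 26.5) and 30.1 (29.8 to 30.5) such UMIs of 10000, against 104.5 in cluster 11, 152 in cluster 10 and 202 in cluster 9. Cluster 9 stood above cluster 1 by 2.95 on the log2 scale (2.93 to 2.97). Mki67, a gene of dividing cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716450), was at 11.6 CPM in cluster 1, 13.6 in cluster 6, 321 in cluster 11 and 932 in cluster 9. Clusters 9 and 10 also had the deepest cells, with medians of 13666 and 14257 UMIs, and a doublet caller marked 19.8% and 15.1% of their cells. The marked share was 9.20% in cluster 6 and 4.25% in cluster 1.

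**Figure D1:**
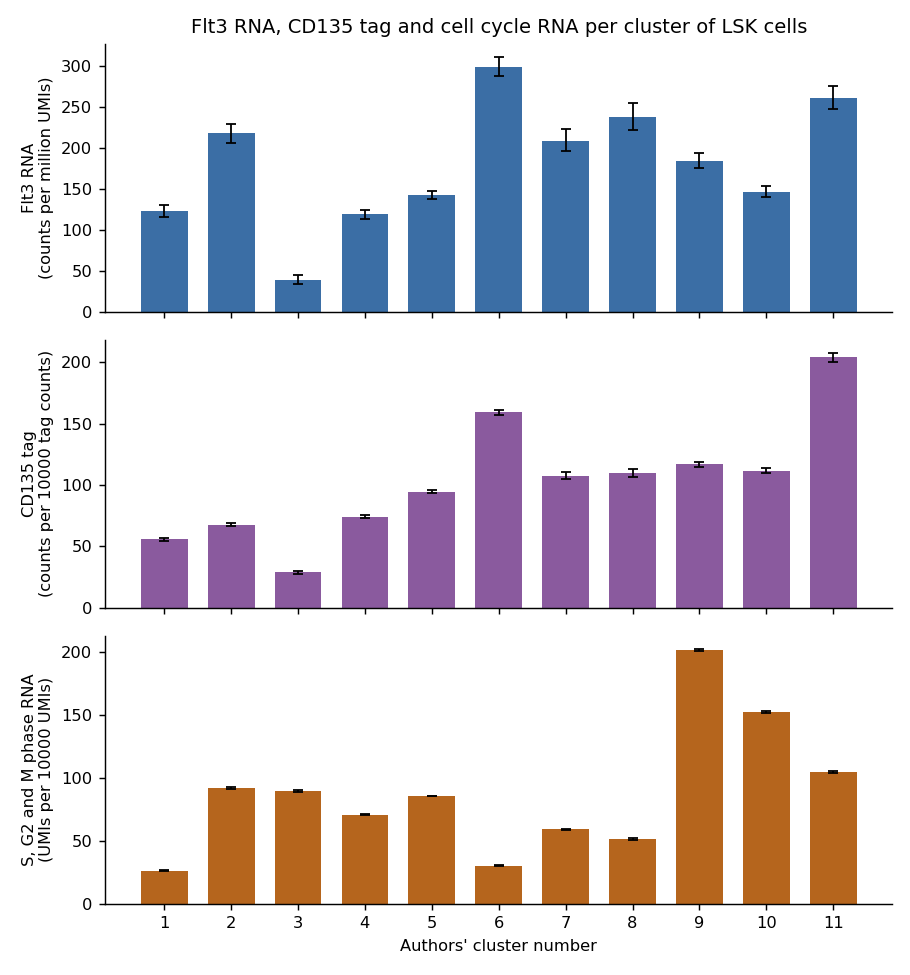
Flt3 RNA (CPM), CD135 tag (counts per 10000 tag UMIs) and S, G2 and M phase RNA (UMIs per 10000) in each of the authors' 11 clusters, as bars with exact 95% Poisson intervals. Cluster 6 had 299 Flt3 CPM and 30.1 cell cycle UMIs per 10000, and cluster 11 had 261 and 104.5.

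After every cell was thinned to 4000 UMIs, 69.7% of the 1187 cells left in cluster 6 had a Flt3 UMI (67.0% to 72.3%), 63.1% in cluster 11, 35.6% in cluster 1 and 10.2% (7.95% to 12.9%) in cluster 3. Without thinning the shares were 83.0%, 91.1%, 43.4% and 23.7%, at median depths of 6016, 8885.5, 5217.5 and 7933 UMIs. Thinning left out 63 cells of cluster 6, 3 of cluster 11, 232 of cluster 1 and 13 of cluster 3. As background, 83 barcodes outside the clusters with at least 1% of their UMIs from immunoglobulin and B cell genes showed a Flt3 UMI in 16.9% of cases at a median of 19894 UMIs. After thinning the share was 5.26% of 57, with an upper bound of 14.6%, and they held 17.2 Flt3 CPM (10.9 to 25.9). The thinned share of cluster 3 lay within that background interval, while its 39.4 CPM lay above it. These barcodes were deeper than the cells of cluster 3 and rich in immunoglobulin RNA, so the background of an LSK droplet may differ.

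The clusters are described by the 5 genes each held highest over the mean of the others, which are no result of their own. Cluster 1 was led by Hbb-bt, other globins and Mllt3, cluster 2 by Hmox1, Cbx6 and Smad5, cluster 3 by Apoe, Sdsl, Bex4, Prkcdbp and Gata2, and cluster 4 by Elane, Ctsg and Mpo. Cluster 5 was led by the S phase gene Ung and by E2f1, cluster 6 by Wfdc17, the chemokines Ccl3 and Ccl4, Btg2 and Ncf1, and cluster 7 by H2-Eb1, Cd74, H2-Aa, Ngp and Lcn2. Cluster 8 was led by Hist1h2bc and Hbb-bs, cluster 9 by the mitotic genes Ube2c, Cdkn3 and Ccnb1, cluster 10 by the histone genes Hist1h1b and Hist1h3b, and cluster 11 by Il7r, Ly6d and Cox6a2. Some of these genes sat in very few cells. The 16 cells richest in Hba-a1 held 95.7% of its UMIs in cluster 1, the 14 richest in Elane held 93.9% in cluster 4, and the 5 richest in Ngp held 98.5% in cluster 7. In cluster 6, by contrast, 87.1% of cells had a Wfdc17 UMI and 86.5% a Btg2 UMI, counted without thinning. The surface tags marked some clusters apart from the RNA. CD150, the product of Slamf1, was at 531 of 10000 tag UMIs in cluster 3 and between 6.39 and 48.6 in the others. CD127, the product of Il7r, was at 43.8 in cluster 11. The tag of MHC class II was at 508 in cluster 7, and the Sca-1 tag was highest in cluster 1 at 1601.

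The first comparison set the 3610 cells with the highest CD135 tag against the 3610 with the lowest and asked how surface Flt3 goes with stem cell, lineage and cell cycle RNA. CD135 tag-high cells held less RNA of stem cell genes, far more of lymphoid genes and less of megakaryocyte and erythroid genes, and they held more cell cycle RNA, not less. Dntt, the terminal transferase of antigen receptor genes, was at 878 CPM against 42.5, a log2 ratio of 4.37 (4.29 to 4.45). Procr, a stem cell surface receptor, was at 15.4 against 50.4 (log2 ratio −1.71, −1.85 to −1.57), and Apoe was at 50.2 against 340.3. Cell cycle UMIs were 103.9 of 10000 against 82.6, a log2 ratio of 0.33 (0.32 to 0.34).

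Of the 25 measured stem cell genes 23 were at least 1.5-fold lower in the tag-high cells and 0 higher, with a median log2 ratio of −1.76 (−1.88 to −1.70). Mecom, a transcription factor needed by stem cells, was at 67.4 against 144, and Hlf at 177 against 321. Of the 21 measured lymphoid genes other than Flt3, 15 were higher and 0 lower (median 1.58, 1.47 to 1.67). Il12a was at 134 against 29.5, Satb1, a chromatin organiser, at 183 against 50.2, Ighm at 369 against 91.5 and Notch1 at 88.6 against 29.6. Il7r, the interleukin 7 receptor, was at 23.0 against 0.331. Flt3 RNA itself was at 231 against 84.8. Megakaryocyte-erythroid genes were lower in 18 of 22 cases and higher in 0 (median −1.93), among them the transcription factor Gata2 at 20.1 against 84.2, its partner Zfpm1 at 23.3 against 66.8, and the platelet integrin Itga2b at 2.42 against 18.0. The granulocyte-monocyte list went both ways, with 4 of 20 genes higher and 5 lower (median −0.12), while its summed RNA was higher in tag-high cells, at 2075 against 1672. Irf8, a factor of monocytes and dendritic cells, was at 69.0 against 13.0 and Plac8 at 1176 against 652, while Mpo, the peroxidase of neutrophil granules, was at 170.1 against 165.

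In the G2 and M phase list 25 of 52 genes were higher in tag-high cells and 0 lower (median 0.58), with Ube2c at 207 against 100.5, Cenpf at 159 against 87.0 and Aurka at 33.7 against 16.9. In the S phase list 0 of 41 passed 1.5-fold (median 0.11). The quiescence list split, with Btg2, an antiproliferative gene, at 465 against 265 and the cell cycle inhibitor Cdkn1a at 19.3 against 10.2, but the inhibitor Cdkn1c at 6.96 against 26.8 and Ndn at 5.39 against 15.4 (2 of 20 higher, 4 lower, median −0.24). Of the dendritic cell genes 4 of 9 were higher (median 0.42), of the interferon genes 1 of 12, Ifi27l2a at 65.2 against 19.6 (median 0.12). Ribosome biogenesis (0 of 16 past 1.5-fold, median 0.01) and oxidative phosphorylation (0 of 13, median 0.02) were level, as were glycolysis (1 of 13 lower, median −0.13), G1 cyclins and kinases (1 of 10 lower, median −0.05) and immediate early and heat shock genes (3 of 15 higher, median −0.07). Outside the lists the largest ratios in tag-high cells belonged to Clec12a, a C-type lectin receptor, at 58.1 against 7.95, Wfdc17, Cnn3, Ncf1, Ccl3, Tpm4 and the activation marker Cd69 at 477 against 155. In tag-low cells they belonged to Sdsl, Gng11, Serpina3g and the tetraspanins Cd63, at 118 against 317, and Cd9, and to Hacd4.

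Markers of other cell types moved with the tag as well. In tag-high cells 5 of 7 mature B cell genes were higher (median 0.69, but 0.049 as a mean over cells), 2 of 5 T and NK cell genes, with Lck at 41.0 against 14.7 and 1 gene the other way (median 0.15, but −0.33 without the called doublets), and 2 of 8 neutrophil genes (median 0.13, but −0.0019 as a mean over cells). In tag-low cells 7 of 8 erythroid genes (median −0.92, or −2.16 without the called doublets and −1.43 as a mean over cells), 4 of 5 endothelial and stromal genes (median −1.04), 4 of 7 mast, basophil and eosinophil genes (median −0.99, with 1 the other way) and 3 of 7 monocyte and macrophage genes (median −0.36, or −1.17 as a mean over cells, with 2 the other way) were higher. The 36 tag-low cells richest in Elane held 99.0% of its UMIs there, so that Elane and genes like it speak for few cells. Over single cells, the median was 21.8 stem cell list UMIs of 10000 in tag-high against 37.6 in tag-low cells, 32.5 against 15.5 for the lymphoid list, 6.55 against 14.4 for the megakaryocyte-erythroid list and 18.4 against 12.4 for the granulocyte-monocyte list.

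The tag-high cells came mostly from cluster 6 (23.6%), cluster 5 (19.0%) and cluster 11 (13.0%), and the tag-low cells from cluster 1 (25.6%), cluster 4 (17.1%), cluster 5 (15.8%) and cluster 3 (15.3%). Within clusters the differences shrank, to −0.80 for the stem cell list, 0.75 for the lymphoid list and 0.10 for cell cycle RNA, averaged over 9 clusters. The lymphoid median was 0.77 with all barcodes, and the cell cycle ratio was 0.20 on a plain log scale of the tag. The groups are ranges of a continuous level, with 954 and 976 cells within 0.1 of the lower and upper border, and had median depths of 9073 and 6939.5 UMIs.

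**Figure D2:**
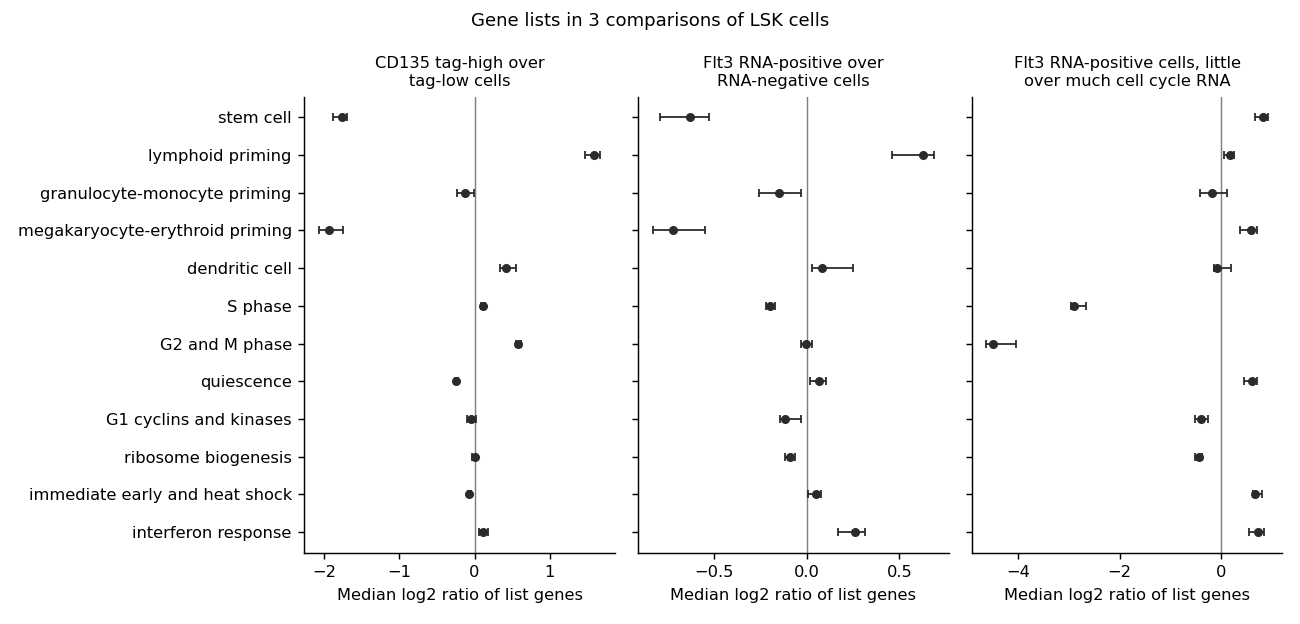
Median log2 ratio of CPM over the genes of 12 lists (points, with 95% intervals for counting error) in CD135 tag-high over tag-low cells, Flt3 RNA-positive over RNA-negative cells, and Flt3 RNA-positive cells with little over much cell cycle RNA. The horizontal scales differ between panels. The stem cell list lay at −1.76, −0.63 and 0.84, and the S phase and G2 and M phase lists of the last panel are fixed by how its groups were split.

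The second comparison split the cells by Flt3 RNA instead of protein, at 4000 UMIs per cell. The 4610 cells with a Flt3 UMI held more lymphoid RNA and less stem cell and megakaryocyte-erythroid RNA in sum than the 5576 cells without, in the same directions as the tag split but with smaller ratios. Cell cycle RNA was nearly level, at 71.9 against 76.4 UMIs of 10000, a log2 ratio of −0.09 (−0.10 to −0.08). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525) was at 535 against 254 CPM, a log2 ratio of 1.08 (1.03 to 1.13), and Apoe had a log2 ratio of −1.19 (−1.27 to −1.11).

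Of the 21 measured lymphoid genes 11 were higher in Flt3 RNA-positive cells and 0 lower (median 0.63, 0.46 to 0.69), with Satb1 at 150.2 against 90.1, Il12a at 103 against 61.8, Notch1 at 76.0 against 47.4 and Ighm at 276 against 174. Of the 25 stem cell genes 13 were lower and 0 higher (median −0.63, −0.79 to −0.53). Pdzk1ip1 was at 27.5 against 51.1 and Mllt3 at 36.1 against 55.9, while Hlf, at 290 against 295, and Mecom, at 102 against 127, stayed within 1.5-fold. Megakaryocyte-erythroid genes were lower in 13 of 22 cases (median −0.73), with Gata2 at 35.0 against 60.2. The S phase list had 1 of 41 genes lower (median −0.20) and the G2 and M phase list 0 of 52 past 1.5-fold, with Mki67 at 185.0 against 185.3. Outside the lists Wfdc17 was at 205 against 110.1, Cd69 at 384 against 250.3 and Gng11 at 44.1 against 71.4. In the positive cells erythroid markers were lower in 7 of 8 cases (median −1.29), mast, basophil and eosinophil markers in 4 of 6 (median −1.57) and neutrophil markers in 4 of 8, with 1 higher (median −0.69), and T and NK cell markers were higher in 3 of 5 (median 0.62). Cells with little cell cycle RNA, meaning at most 13 such UMIs of 4000, made up 38.2% of Flt3 RNA-positive cells (36.8% to 39.6%) and 33.8% of the others (32.6% to 35.1%). Within clusters the stem cell median was −0.14, the lymphoid median 0.24 and the cell cycle ratio −0.06, and with only genes of at least 100 UMIs the stem cell median was −0.42. Over single cells the median was 25 against 17.5 lymphoid list UMIs of 10000 and 27.5 against 30 for the stem cell list, with no difference for the megakaryocyte-erythroid list, 10 against 10. A count of 0 Flt3 UMIs at this depth does not show that a cell lacked Flt3 RNA.

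The third comparison set the 1588 Flt3 RNA-positive cells with the least cell cycle RNA against the 1545 with the most. Few such UMIs do not show how fast a cell divides, so slow cycling itself was not measured. The cells with little cell cycle RNA held more RNA of stem cell, quiescence, immediate early and interferon genes. Flt3 was at 395 against 371 CPM, with a floor set by the choice of cells that had a Flt3 UMI. Procr (ENSMUSG00000027611, chromosome 2, 155751125 to 155755478) was at 51.5 against 20.1, a log2 ratio of 1.36 (1.06 to 1.67). Txnip, which curbs glucose uptake, was at 500.2 against 199, and Mpo was at 54.5 against 203 (log2 ratio −1.89, −2.07 to −1.72). Lymphoid genes as a group differed little.

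Of 19 measured stem cell genes 15 were higher in the cells with little cell cycle RNA and 1 lower (median 0.84, 0.68 to 0.94), among them Pdzk1ip1 at 44.2 against 14.6, Ifitm1 at 1075 against 496, Hlf at 378 against 207 and Mecom (ENSMUSG00000027684, chromosome 3, 29951296 to 30509759) at 135 against 75.4. The lymphoid list split into 3 of 21 genes higher, with Lax1 at 45.2 against 20.6 and Gimap6 at 446 against 245, and 5 lower, with Il7r at 8.97 against 18.1 (median 0.18, 0.07 to 0.25). Dntt was at 449.9 against 653. In the quiescence list 11 of 20 genes were higher (median 0.62), such as Btg2 at 610.4 against 328, Btg1 at 227 against 119 and Klf6 at 866 against 473, and 1 was lower, Cdkn2c at 5.20 against 22.2. Immediate early and heat shock genes were higher in 10 of 15 cases (median 0.68), with Fos at 2405 against 1301 and Junb at 718 against 343, and 3 were lower, among them the chaperone Hsp90aa1 at 713 against 1364. Interferon genes were higher in 8 of 12 cases (median 0.73), with Ifit1 at 31.8 against 8.90 and Irf7 at 59.0 against 26.1.

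In the same cells ribosome biogenesis was lower in 5 of 16 genes (median −0.44), with Nop58 at 179 against 279, and oxidative phosphorylation in 4 of 13 (median −0.43), while glycolysis had 3 of 13 lower and 2 higher (median −0.23). Of 10 G1 cyclins and kinases 5 were lower, with Ccne1 at 0.315 against 9.06, and 1 was higher, Mycn at 46.9 against 15.2 (median −0.39). Megakaryocyte-erythroid genes were higher in 8 of 15 cases (median 0.60), with Gata2 at 43.0 against 27.5 and Pf4 at 14.8 against 6.47, and granulocyte-monocyte genes were lower in 5 of 14 and higher in 2 (median −0.18). Outside the lists Ltb, a cytokine of the tumour necrosis factor family, was at 358 against 99.4, Wfdc17 at 312 against 96.0 and Samhd1 at 114 against 41.7. The genes with the largest ratios the other way, such as Esco2 and Kif4, belong to dividing cells and follow from the split. Neutrophil markers were lower in 7 of 7 cases (median −2.12), and the 15 cells richest in Camp held 98.5% of its UMIs among the cells with much cell cycle RNA. Erythroid markers were lower in 3 of 5 cases and higher in 1 (median −1.84, −2.07 to −1.49, or −1.16 without the called doublets), but their summed RNA was at 977 against 926 and their median over single cells at 7.5 against 5 UMIs of 10000, so the direction depends on the measure. Before thinning the groups had median depths of 5759.5 and 12677 UMIs. Of the cells with little cell cycle RNA 35.6% lay in cluster 6 and 24.6% in cluster 1. Those with much lay mostly in other clusters, with 28.1% in cluster 5, 21.8% in cluster 10 and 20.3% in cluster 9. Within clusters the stem cell median was 0.71, averaged over only 3 clusters. Over single cells the median was 35 stem cell list UMIs of 10000 against 20. Over all thinned cells 341 sat exactly at the border of 13 cell cycle UMIs.

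**Figure D3:**
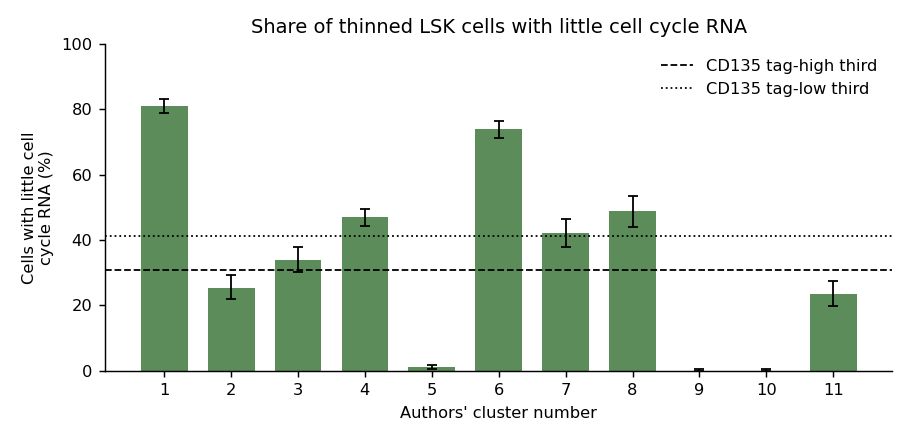
Share of cells with at most 13 cell cycle UMIs of 4000 (percent of thinned cells) in each of the authors' 11 clusters, as bars with exact 95% binomial intervals, with lines for CD135 tag-high and tag-low cells. Clusters 1 and 6 lay at 81.1% and 74.0%, and the lines at 30.9% for tag-high and 41.2% for tag-low cells.

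Cells with little cell cycle RNA were most frequent in clusters 1 and 6, with 81.1% (79.0% to 83.1%) and 74.0% (71.4% to 76.4%) of thinned cells, against 23.5% in cluster 11 and 0 of 809 in cluster 10, with an upper bound of 0.455%. The 3 comparisons of clusters were chosen after these values were seen, and the clusters' own leading genes are not singled out in them but stay in the list counts. Cluster 1 is called stem cell gene-rich from the stem cell list itself, which was highest there of all clusters, at 5749 CPM. Its differences in that list therefore partly restate how it was named. How far the clusters were drawn on the listed genes is not known here. Cluster 6 against cluster 1 set the Flt3-rich against the stem cell gene-rich cluster at similar summed cell cycle RNA (log2 ratio 0.21, 0.18 to 0.23). The median log2 ratio was 0.43 for the S phase list and 0.16 for the G2 and M phase list. Cluster 6 held 22 of 25 stem cell genes lower (median −2.08, −2.32 to −1.78), with Procr at 24.6 against 103.9, Hlf at 253 against 617 and Mecom at 84.8 against 250.2. It held 15 of 21 lymphoid genes higher, Flt3 among them (median 2.46-fold, a log2 interval of 1.22 to 1.52, and a log2 ratio of 1.49 without Flt3), with Dntt at 600.2 against 24.5, Satb1 at 231 against 48.4 and Ighm at 419 against 91.3. Granulocyte-monocyte genes were higher in 10 of 15 cases (median 1.69), with Irf8 at 47.4 against 8.57, Plac8 at 1074 against 333 and Mpo at 65.6 against 16.2. In the quiescence list 5 of 20 genes were lower and 2 higher (median −0.17), with Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461059) at 6.72 against 44.7 and Ndn at 5.76 against 27.5. The summed RNA of that list went the other way, at 5548 CPM in cluster 6 against 5122 in cluster 1. Outside the lists Cd69 was at 569 against 111 and Cd48, a surface marker used to set progenitors apart from stem cells, at 130 against 25.9. Neutrophil markers were higher in 8 of 8 cases (median 3.12, or 2.00 as a mean over cells) in cluster 6, where the 12 cells richest in S100a9 held 90.1% of its UMIs. Erythroid markers were lower in 7 of 8 (median −4.33, or −3.54 as a mean over cells). In cluster 1 the 16 cells richest in each gene held 95.7% of Hba-a1, 95.8% of Hbb-bs and 41.1% of Hbb-bt UMIs. T and NK cell markers were higher in 3 of 3 (median 3.77), with 91.4% of the Ccl5 UMIs of cluster 6 in 12 cells.

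Cluster 6 against cluster 11 set the Flt3-rich clusters against each other. Cluster 6 held 30.1 against 104.5 cell cycle UMIs of 10000 (log2 ratio −1.79, −1.81 to −1.77) and 16 of 17 measured stem cell genes higher (median 2.12, 1.66 to 2.39), with Procr at 24.6 against 2.46, Hlf at 253 against 32.3 and Mecom at 84.8 against 24.4. Lymphoid genes, Flt3 included, were lower in 9 of 22 cases and higher in 1 (median −0.24, or −0.30 without Flt3), with Dntt at 600.2 against 2673 and Blnk, an adaptor of B cell receptor signals, at 6.00 against 43.3, but Satb1 at 231 against 262 and Mef2c at 611 against 668. Of the quiescence genes 11 of 20 were higher in cluster 6 (median 0.85), with Txnip at 420 against 143 and Klf6 at 843 against 343. Immediate early and heat shock genes were higher in 11 of 15 cases (median 0.93), with Fos at 2632 against 1333. The megakaryocyte-erythroid list was higher in cluster 6 as well (median 1.51 over 14 genes). The granulocyte-monocyte list had a median of 0.61 over 15 genes. Its summed RNA over the whole list went the other way, at 1916 CPM in cluster 6 against 2640 in cluster 11. Of 6 mature B cell genes 4 were lower (median −3.46). Erythroid markers were lower in 3 of 5 cases and higher in 1 (median −2.96, but 0.73 without the called doublets), and neutrophil markers were higher in 5 of 8 (median 0.82, but −1.14 as a mean over cells).

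Cluster 3 against cluster 1 set the CD150-rich against the stem cell gene-rich cluster. Cluster 3 held 16 of 22 megakaryocyte-erythroid genes higher (median 1.07, 0.81 to 1.24), with Itga2b at 36.8 against 7.59, Zfpm1 at 112 against 60.4 and Vwf at 12.2 against 5.10. It held 89.7 against 26.1 cell cycle UMIs of 10000 (log2 ratio 1.78, 1.76 to 1.80). Stem cell genes split into 5 higher and 5 lower of 25 (median −0.12). Slamf1 (ENSMUSG00000015316, chromosome 1, 171767131 to 171801184), which codes for CD150, was at 19.8 against 1.95, and Tek at 8.79 against 4.55. Procr was at 40.3 against 103.9, Hlf at 245 against 617 and Ly6a at 131 against 309. Interferon genes were lower in 7 of 12 cases and higher in 0 (median −0.65), with Ifit1 at 13.3 against 33.8. Lymphoid genes, Flt3 included, were lower in 9 of 17 cases and higher in 1 (median −0.72, or −0.63 without Flt3), with Flt3 at 39.4 against 123. Erythroid markers ran against the megakaryocyte-erythroid list, with 7 of 8 lower (median −3.64, −4.26 to −2.48, or −3.07 as a mean over cells). Few cells carried much of this. In cluster 1 the 16 cells richest in each gene held 95.7% of Hba-a1, 95.8% of Hbb-bs and 41.1% of Hbb-bt UMIs. Of the quiescence genes 7 of 20 were lower and 2 higher (median −0.31), and of the dendritic cell genes 4 of 8 were lower (median −0.69). Neutrophil markers were higher in 6 of 6 cases (median 3.35, or 2.05 as a mean over cells), and 6 cells held 94.9% of the Ngp UMIs of cluster 3.

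The last comparison used the surface marks by which LSK cells are often split, CD135 and CD150. The 5895 CD135+ CD150− cells held slightly more cell cycle RNA than the 1367 CD135− CD150+ cells, 97.0 against 87.7 UMIs of 10000, a log2 ratio of 0.15 (0.14 to 0.15). They held 20 of 24 stem cell genes lower (median −1.79), 16 of 21 lymphoid genes higher (median 1.79), 18 of 22 megakaryocyte-erythroid genes lower (median −1.98) and 11 of 20 granulocyte-monocyte genes higher (median 0.68). Dntt was at 629 against 31.7, Cd52 at 257 against 74.5, Mpo at 176 against 58.1, Apoe at 64.2 against 623, Pf4 at 6.74 against 32.2 and Cdkn1c at 8.26 against 40.7. In the G2 and M phase list 2 of 52 genes were higher (median 0.24), with Mki67 at 291 against 262, and in the quiescence list 2 of 20 were higher and 4 lower (median −0.21). Of other cell types, dendritic cell genes were higher in 7 of 10 cases (median 0.74), T and NK cell genes in 3 of 5, with 2 lower (median 0.86, or 1.81 as a mean over cells), neutrophil genes in 2 of 8 (median 0.41, but −0.27 as a mean over cells), and endothelial and stromal genes were lower in 3 of 5 (median −0.74). Erythroid genes were lower in 2 of 8 cases (median 0.077, but −0.54 without the called doublets). The 3344 CD135− CD150− cells held 81.1 cell cycle UMIs of 10000 and the 222 CD135+ CD150+ cells 99.4. Cells with little cell cycle RNA made up 32.9% of CD135+ CD150− and 41.8% of CD135− CD150+ cells. Over single cells the median was 25.7 against 43.8 stem cell list UMIs of 10000, 7.88 against 19.0 megakaryocyte-erythroid list UMIs and 5.11 against 8.97 erythroid list UMIs.

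The cell cycle ratio of this pair was 0.01 on a plain log scale of the tags and 0.30 when all cells were thinned and those with a Cd48 UMI left out of the CD135− CD150+ side, a value that holds both changes. The groups are ranges, with 1045 cells within 0.1 of the CD135 border and 233 within 0.1 of the CD150 border.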

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

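The tests of clusters drawn on cell cycle genes, of free macrophage RNA and of whole antibody-making cells, and the unrelated tags without 1 cell, were chosen only after the results were seen. The labels put all cells in 1 pool and give no groups, so no biological explanation was tested.

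Signals outside the clustered cells drew attention. Immunoglobulin and B cell genes made up at least 1% of the UMIs in 83 of the 1558 barcodes outside the clusters and in 8 clustered cells, and in those 83 Igkc stood at 450008 CPM, against 151 in clustered cells. Mitochondrial genes made up at least 50% of the UMIs in 9.05% of the unclustered barcodes, 141 in number, and in 0 clustered cells. Neutrophil genes made up at least 5% of the UMIs in 1.60% of unclustered barcodes and in 0.175% of clustered cells.

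The immunoglobulin-rich barcodes also held 29467 CPM of Jchain, 1346 of Mzb1, 1059 of Xbp1 and 129 of Sdc1, against 10.3, 4.98, 36.6 and 14.3 in clustered cells. Free RNA in every droplet would have spread these counts, yet 94.7% of all Igkc, Ighm and Jchain UMIs of the matrix sat in the 83 barcodes. Whole antibody-making cells that passed the sort may be the source, since Xbp1, Mzb1 and Prdm1, which such cells need, were 57.3-fold higher there than in clustered cells. The sort for Kit and Sca-1 should remove such cells, and the barcodes carried fewer of these tags, with a median of 12 Sca-1 tags against 87 and 1 Kit tag against 10. Fewer tags were not particular to these markers, since CD44 was at 32 against 140 and CD27 at 4 against 166. Some tags went the other way, such as CD55 at 13 against 7 and Ly6C at 7 against 3.

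Cluster 2 held RNA and tags of macrophages, which the lineage and Kit gates should remove. The macrophage list stood at 317 CPM there and 29.1 in the other clusters, with Hmox1 at 61.5 against 8.30, C1qa at 49.9 against 4.15 and Vcam1 at 38.0 against 2.05, and after thinning 39.1% of its cells had a UMI of the list against 7.80% elsewhere. Free macrophage RNA in every droplet would give all clusters a like level, but C1qa, C1qb and C1qc together were 11.7-fold higher in cluster 2. Doublets with whole macrophages cannot be told apart from the rest, because called doublets held 11.1% of the list's UMIs but no barcode carried over 2.16% of such RNA from which the caller could build a macrophage doublet, so its low share excludes nothing. Unspecific antibody binding and macrophage material attached to LSK cells may both contribute: the relative rise per cell of 6 unrelated tags was 139% of that of F4/80, CD106 and CD206, or 67.2% without 1 cell with 3375 unrelated tags, and its cells with a macrophage UMI carried 1.50 times the F4/80, CD106 and CD206 tags of those without, right at the bound set for attached material.

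Little cell cycle RNA in cluster 6, the cluster with the highest Flt3 RNA, is the pattern closest to the series title. It does not show how fast these cells divide. A stress response during isolation as its cause stays open. The 406 cluster 6 cells with the fewest immediate early and heat shock UMIs held 30.2 cell cycle UMIs of 10000 (29.4 to 31.1), below the bound of 45 set for it. But they were the lowest only within cluster 6, with up to 52 such UMIs each, so they are not shown to lack the response. The list stood at 14680 CPM in cluster 6 and 14433 in cluster 1, against 8374 to 12227 in the other clusters. Lower depth as an effect of counting alone is argued against by the cells thinned to the same total. There 74.0% of cluster 6 cells (71.4% to 76.4%) had little cell cycle RNA, against 35.8% of all clustered cells. Lower depth of the cells themselves stays open in part. Among cells of 5000 to 7000 UMIs cluster 6 held 26.5 against 37.8 cell cycle UMIs of 10000 in the others. That log2 ratio of −0.52 (−0.55 to −0.48) lay between the bounds for either outcome. The others included cluster 1, which held 26.1 over all its cells. The clusters did part cells by cell cycle RNA. Cluster 5 was led by the S phase gene Ung, cluster 9 by the mitotic gene Ube2c and cluster 10 by the histone gene Hist1h1b. In clusters 9 and 10, 0% of thinned cells had little cell cycle RNA. How far that parting accounts for the low level in cluster 6 stays open. Without clusters the share of cells with little cell cycle RNA differed by −10.3 percentage points between CD135 tag-high and tag-low cells. It differed by 4.42 the other way between Flt3 RNA-positive cells (38.2%) and RNA-negative cells (33.8%). The genes behind the authors' clusters are not given in the sources used here, so how far they shaped the pattern was not tested.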

How the results depend on the processing

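The tests with clusters 2 and 7 left out and with Cd48 were chosen only after the data were seen. Of 110 alternatives, 97 planned and 13 added, 110 kept the direction of the main value, 65 stayed within its counting interval, 45 lay outside it and 0 reversed. The cause was not tested. Some of these outcomes were fixed in advance, so the counts overstate the stability. A range from the highest to the lowest cluster cannot reverse. Leaving out clusters 2 and 7 cannot change a range between other clusters. In the splits by Flt3 RNA all cells were thinned to the same total, so the mean over cells equals the main value. All values are log2 ratios unless a unit is given. No paired analysis was possible because the pool gave 1 sample.

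The highest and lowest clusters stayed the same under every alternative run for Flt3 RNA, the CD135 tag and cell cycle RNA. With all barcodes, or with clusters left out, this was fixed in advance. Barcodes outside the clusters enter no cluster, and no cluster left out was the highest or lowest. The range from highest to lowest cluster was 3.46 for Flt3 RNA, 3.08 for cell cycle RNA and 3.07 for the tag without called doublets. It was 3.14 for Flt3 RNA and 3.02 for cell cycle RNA as means over cells, 3.30 and 3.01 after thinning, and 2.87 for cell cycle RNA without ribosomal and mitochondrial genes.

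In CD135 tag-high over tag-low cells, removal of called doublets gave 0.38 for cell cycle RNA, −2.02 for the stem cell list and 1.74 for the lymphoid list. The outer 25% of cells by tag on each side gave 0.38, −2.09 and 1.83, ratios within clusters 0.10, −0.80 and 0.75, and clusters 2 and 7 left out 0.36, −1.89 and 1.68. Means over cells gave 0.38 for cell cycle RNA and −2.03 for the stem cell list, and a log scale of the tag 0.20 and −1.90. Totals without ribosomal and mitochondrial genes gave 0.34 for cell cycle RNA, and all barcodes gave 0.77 for the lymphoid list.

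In Flt3 RNA-positive over RNA-negative cells, the deeper thinning gave −0.061 for cell cycle RNA and −0.83 for the stem cell list, ratios within clusters gave −0.056, −0.14 and 0.24 for the lymphoid list, and clusters 2 and 7 left out gave −0.066 for cell cycle RNA. A minimum of 100 UMIs per gene gave −0.42 for the stem cell list, with 20 genes left, and removal of doublets 0.70 for the lymphoid list. In Flt3 RNA-positive cells with little over much cell cycle RNA, the stem cell list gave 0.94 without doublets, 0.60 with the deeper thinning and 0.94 without clusters 2 and 7, and the lymphoid list 0.26 without ribosomal and mitochondrial genes and 0.25 with the deeper thinning.

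Cell cycle RNA of CD135+ CD150− over CD135− CD150+ cells gave 0.21 without doublets, 0.18 as a mean over cells, 0.16 without ribosomal and mitochondrial genes, 0.011 on a log scale of the tags, 0.17 without clusters 2 and 7 and 0.30 with all cells thinned and Cd48 cells left out. Depth limits the shares of cells: the immunoglobulin-rich barcodes, with 17.2 Flt3 CPM, had a Flt3 UMI in 5.26% of the 57 thinned to 4000 UMIs.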

Other observations

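Cluster 7 held MHC class II and neutrophil RNA, each largely in few cells. Of its 528 cells of at least 4000 UMIs, 18 had at least 10 UMIs of MHC class II genes after thinning and held 59.6% of such UMIs in the cluster, with an I-A/I-E tag level of 2362 of 10000. In the same way 4 cells had at least 10 neutrophil list UMIs and held 96.6% of those. Neutrophil RNA in other clusters sat in few cells too, with 12 cells holding 100% of the Retnlg UMIs of cluster 6 and 6 cells 97.6% of the Lcn2 UMIs of cluster 3.

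RNA and tag of the same molecule were set side by side over the 11 clusters. Slamf1 RNA and the CD150 tag were both highest in cluster 3, Il7r RNA and the CD127 tag in cluster 11, and Ly6a RNA and the Sca-1 tag in cluster 1. Cd34 RNA and the CD34 tag did not match, with RNA highest and tag lowest in cluster 6 and a rank correlation of −0.6 over the clusters. The tag varied little, from 78.8 to 105.9 of 10000 tag UMIs, while the RNA ran from 234 to 604 CPM. Over cells the rank correlation was −0.0031. The Ly6D tag had 0 UMIs over all barcodes, although Ly6d RNA was among the leading genes of cluster 11. Of all clusters, cluster 2 had the highest median of tag UMIs per cell, 1637.5 against 972 over all clustered cells, so its CD135 tag of 67.9 per 10000 corresponds to a median of 11 counts per cell, against 13 in cluster 6.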
